A study of Mus musculus with 24 samples.

How the data were processed

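RNA was measured in the rostroventral neural tube, the lower front part of the tissue that forms the brain, dissected from single C57BL/6J mouse embryos on embryonic day 9. Per the labels' protocols, dams received 1 intraperitoneal injection of ethanol at 2.9 g/kg (25% by volume in Lactated Ringer's solution) or that vehicle alone at a matched volume, 1.5 ml per 100 g of body weight, and embryos were taken 2 or 4 h later. The groups were matched on somite number, with 19 to 20 somites at 2 h and 20 to 21 at 4 h. No more than 2 embryos came from any litter, and the labels do not say which embryos were littermates, so the p-values treat littermates as independent. Libraries came from a low-input whole-transcript kit, were run in 6 pools with 1 sample of each group in each pool and 1 pool per lane, and were read as 50 bp pairs. The labels do not tie replicate numbers to pools. The source field of the labels says whole embryo while the protocol describes the dissected neural tube, and the protocol is followed here. The 24 libraries fall into 4 groups of 6: vehicle at 2 h, ethanol at 2 h, vehicle at 4 h and ethanol at 4 h.

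The deposited table holds 1 value per gene symbol and library on a log2-like scale, the variance-stabilizing transformation by the abbreviation in the table's name. Per the submitters' processing notes, the tools were cutadapt 1.12, STAR 2.5.2b, Salmon, DESeq2 1.22.2 and limma, and the genome build was mm9; the notes give no role or order. The values are not plain transformed counts. Every gene's mean over the ethanol 2 h libraries was 0 to within 1.3e-08, and the matrix of 24 libraries had rank 21. Values of this kind result when an intercept and 2 further covariates are fitted beside the groups and subtracted; what the 2 covariates were is not given in the sources used here. A gene's expression level and the depth of each library are therefore unknown, and no counting interval or floor is given. Differences between groups are in units of the deposited log2 scale, which compresses changes of low-count genes, so they are not converted to folds.

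Of 24444 rows, 5822 held a constant and were left out, which left 18622 genes. The design fixed before the data were examined was limma with a mean-variance trend and a filter on low values, on 4 group means without covariates. Neither trend nor filter can be had from centred values, so the test was limma 3.58.1 (R 4.3.3) without a trend. The 2 removed dimensions were recovered, as far as they vary within groups, from the directions in which the table has no variance (singular values below 1e-06), and were kept in the fit, which left 18 residual degrees of freedom; a fit without them is among the alternatives. Of the 2 dimensions, 1.42 lay in the ethanol 2 h libraries. The part of the removed covariates that differed between groups is lost, so standard errors of comparisons, those with the ethanol 2 h group above all, can be too small. A second count, chosen after seeing the data, is therefore given beside each main one: the moderated statistics were divided by their robust spread over all genes (the widened spread), by 1.34 for ethanol at 2 h, 1.18 for ethanol at 4 h, 1.22 for the interaction, 1.01 for time in vehicle and 1.45 for time in ethanol. Tests were two-sided, with Benjamini-Hochberg adjustment over the 18622 genes and a threshold of 0.05. There were 5 such comparisons.

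The procedure was tested on simulated data for the ethanol comparison at 2 h, with 18622 genes of which 200 were changed. Genes were drawn independently and with equal spread in all libraries. The real genes are correlated and the real libraries unequal, so the rates below need not hold for them. With no between-group part of the removed covariates, it recovered 34.3% of genes changed by 0.25, 88.1% of those changed by 0.5 and 98.5% of those changed by 1, and 2 of 149 calls were false. With a shift of 0.25 between groups in the removed covariates, 46 of 208 calls were false, and with a shift of 0.5, 768 of 930. The widened spread gave 13 false calls of 157 and 5 of 114 in those cases.

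Gene lists were fixed before the data were examined: 28 pathway lists and 15 marker lists, with 881 gene names. Of these names 16 had no row, among them all mitochondrially encoded transcripts, and 2 were constant, which left 42 lists with at least 5 genes. Lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Camera compares a list with the other genes, while directional fry asks whether its genes move on balance in 1 direction. Mixed fry, also fixed beforehand, asks whether they move in either direction. The mean of each list per library was also compared by exact two-sided permutation over all 924 splits of 12 libraries. The smallest possible p is 0.00216, and the test was added after seeing the data. Because covariates appear to have been subtracted around the real groups, this permutation can favour the real split and does not exclude chance. The share of the 2 h genes with the same sign at 4 h was set against all 462 distinct splits of the 4 h libraries by exact permutation, also after seeing the data. Counts of members "adjusted over the list alone" use the adjustment within the list. The named genes follow a rule fixed before the data were examined: per ethanol comparison, the 12 largest rises and 12 largest falls among genes that passed, without clone or model names; for the interaction, the 6 smallest p-values in each direction; for time, the 6 largest changes in each direction; up to 10 genes that passed in both ethanol comparisons; and for each list up to 4 members that passed, or else up to 2 as values. A gene named outside this rule is said to be so where it appears.

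Transcript lengths and GC content came from GENCODE annotation of another genome build, matched by symbol for 97.5% of the genes tested; no coordinates are printed because the builds differ. Alternatives fixed beforehand were robust moderation, library weights, fits on the compared groups alone, median centring, quantile normalization, the replicate number as a block, a sex-linked covariate, other thresholds and leaving out each library. Alternatives chosen after seeing the data were the fit without the removed dimensions, a filter on residual spread, removal of a length and GC trend, marker means as covariates, the widened spread and leaving out ethanol 2 h libraries 2 and 3 together. H2-D1 and H2-L are near-identical in sequence and may report the same transcripts, so their values need not be independent. Several globin genes are near-identical copies, and Hspa8 has many processed pseudogenes. Values of all these genes are uncertain where reads were shared.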

Results

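The series addressed how the early neural tube responds in its transcripts within hours of a single exposure to alcohol. RNA was sequenced from the rostroventral neural tube of 24 mouse embryos, 6 in each of 4 groups: vehicle and ethanol, each at 2 h and 4 h after injection of the dam. In a separate cohort of 6 dams, the labels give a blood alcohol concentration of 366.8 ± 30.3 mg/dl (SE) at 30 min and 337.9 ± 18.8 mg/dl at 2 h. Values are on the deposited log2 scale relative to the mean of the ethanol 2 h group, and the depth of the libraries is unknown. The median SD over genes was 0.12 among the ethanol 2 h libraries, 0.09 among the vehicle 2 h libraries and 0.11 in each 4 h group (n = 6 each). Ethanol 2 h replicate 3 had the largest residual SD over genes, 0.26, against at most 0.16 in any other library. Residual SDs are not fully comparable, because the removed dimensions lay unequally in the libraries. Of the 2 dimensions, 0.66 lay in ethanol 2 h replicate 2 and 0.44 in replicate 6, whose residual SDs are therefore too small. Replicate 2 had the smallest, 0.07.

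The first comparison asked which transcripts differed 2 h after ethanol. Bhlhe40, a transcriptional repressor of the clock and hypoxia pathways, was 1.56 ± 0.24 log2 units higher (difference ± SE, n = 6 per group, adjusted p = 0.00122), and Ddit4, an inhibitor of mTORC1, was 1.18 ± 0.15 higher (adjusted p = 0.000197). The early response gene Ier3 rose by 1.42 ± 0.18 and Ciart, a clock repressor, by 1.09 ± 0.14. Among the falls were Rsrp1, which encodes an arginine- and serine-rich protein, at -1.41 ± 0.14 (adjusted p = 1.67e-05), the splicing-related Luc7l at -0.76 ± 0.08 and the constitutive chaperone Hspa8 at -0.73 ± 0.11 (adjusted p = 0.00103). Each of these was shifted in the same direction in all 6 ethanol libraries relative to the vehicle mean.

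In all, 365 of 18622 genes passed at 2 h, 207 higher and 158 lower, with a median size of 0.33 log2 units; 50 differed by at least 0.5 and 8 by at least 1. The other large rises were Arrdc3 (1.19 ± 0.14), an arrestin-domain protein, Stc1 (1.06 ± 0.13), a secreted glycoprotein, Adm (1.01 ± 0.16), which encodes the vasodilator adrenomedullin, and Slc16a6 (0.84 ± 0.08), a monocarboxylate transporter family member. Metallothionein Mt1 rose by 0.83 ± 0.15, Ankrd37 by 0.79 ± 0.14, the lipid droplet protein gene Hilpda by 0.73 ± 0.08 and the ubiquitin ligase gene Trim6 by 0.73 ± 0.09. The other large falls were Flrt2 (-0.66 ± 0.13), Asxl2 (-0.63 ± 0.10), Myc (-0.61 ± 0.11), Zbtb40 (-0.60 ± 0.13), Banp (-0.60 ± 0.14), the protocadherin Pcdh18 (-0.59 ± 0.12), Sall2 (-0.56 ± 0.12), the splicing factor kinase Clk1 (-0.56 ± 0.10) and Neto2 (-0.55 ± 0.09). Adjusted p-values from limma for these genes lay between 1.67e-05 for Slc16a6 and 0.0253 for Banp. With the widened spread 29 genes passed, 19 of them higher; they included Rsrp1, Slc16a6, Luc7l, Hilpda, Arrdc3, Ier3, Stc1, Trim6, Ddit4, Ciart and Hspa8, whereas Bhlhe40 (adjusted p = 0.0523) and Adm (adjusted p = 0.0747) did not pass. The count was 85 without ethanol 2 h replicate 2, 674 without ethanol 2 h replicate 5 and 214 with sex-linked expression as a covariate.

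**Figure D1:**
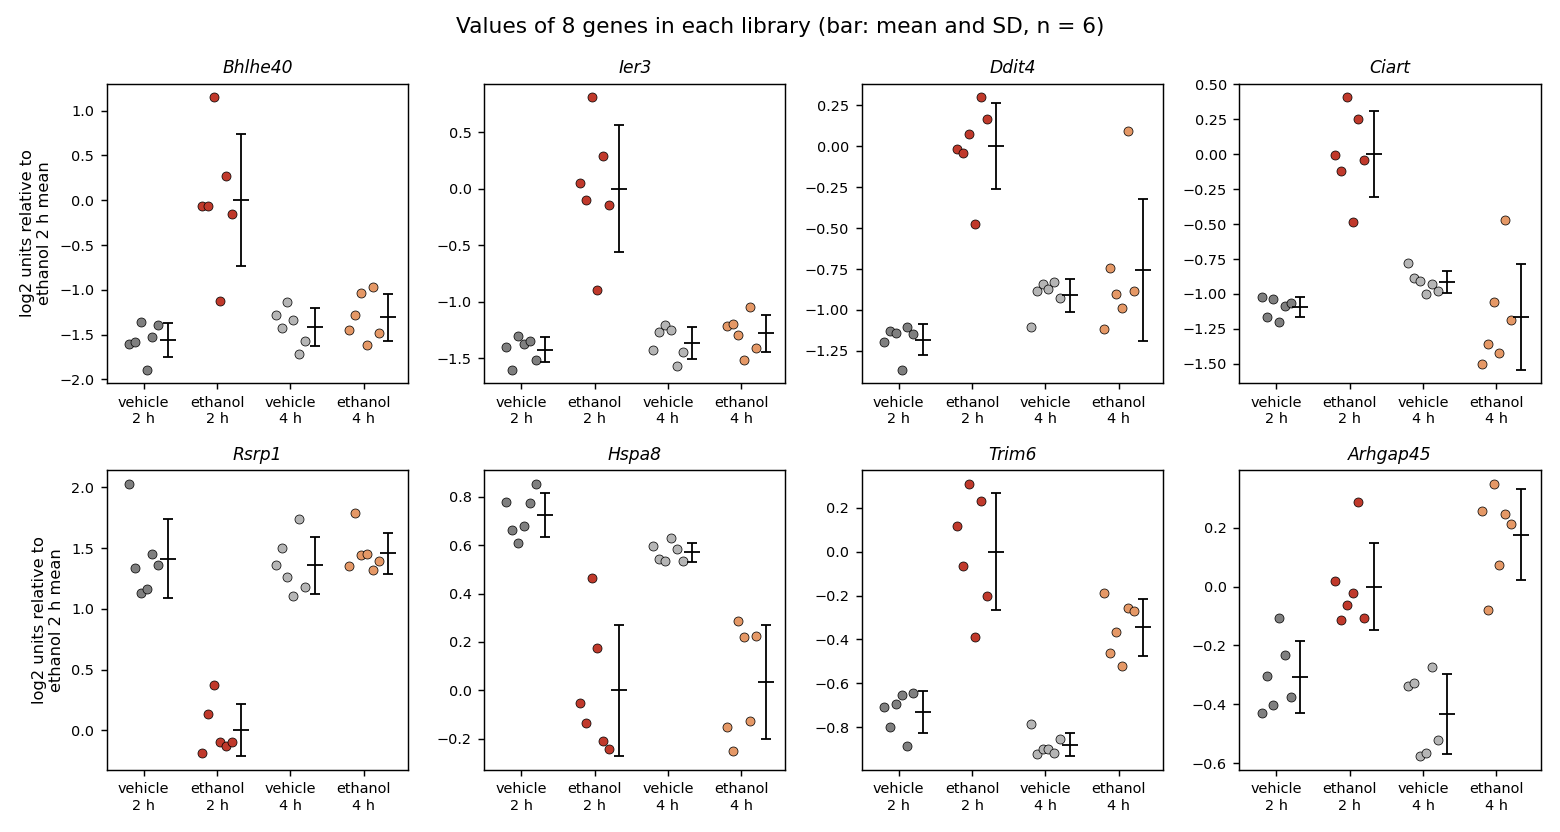
Values of 8 genes in every library, in log2 units relative to the ethanol 2 h mean, by group; points are libraries and bars the mean ± SD (n = 6). Bhlhe40, Ier3, Ddit4 and Ciart were higher and Rsrp1 lower with ethanol at 2 h, Hspa8 was lower and Trim6 higher at both times, and Arhgap45 passed the test at 4 h.

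Among the 42 lists, that of the hypoxia response had the largest mean difference at 2 h (0.41) and the smallest camera p with the preset correlation. Of its 23 measured members 6 rose and none fell over all genes, and 12 rose when adjusted over the list alone; besides Bhlhe40, Ddit4, Adm and Ankrd37 these 6 were the oxygen sensors Egln1 (0.44 ± 0.11) and Egln3 (0.68 ± 0.18), named outside the rule. Its mean was -0.41 ± 0.05 in vehicle and 0.00 ± 0.17 in ethanol (SD, n = 6 each; exact permutation p = 0.00216, the smallest possible, adjusted over 42 lists 0.0152). Camera gave an adjusted p = 2.03e-09 with the preset correlation and an adjusted p = 0.101 with an estimated correlation. The circadian clock list rose (camera adjusted p = 0.000102, adjusted p = 0.0697 with an estimated correlation): 5 of 18 members were higher, among them Bhlhe41 (0.35 ± 0.07) and Rora (0.35 ± 0.07), and 8 when adjusted over the list alone. Among the glucocorticoid targets, Ddit4 and Klf9 (0.32 ± 0.07) of 16 members rose over all genes and when adjusted over the list alone. Camera called the list higher (camera adjusted p = 0.00571, adjusted p = 0.0697 with an estimated correlation). Its mean difference was 0.14 and the median over its members 0.08, with 12 of 16 members above 0 and Ddit4 at 1.18. The list was not tested without Ddit4. The antioxidant list rose (camera adjusted p = 0.00219, adjusted p = 0.134 with an estimated correlation), with 19 of 24 members above 0. Of these, 3 passed over all genes, heme oxygenase Hmox1 (0.47 ± 0.08), Mt1 and Mt2 (0.63 ± 0.15), and 4 when adjusted over the list alone. The integrated stress response list rose (camera adjusted p = 0.000236, adjusted p = 0.101 with an estimated correlation). Of its 32 members 4 rose, including the eIF2α phosphatase subunit Ppp1r15a (0.53 ± 0.09), Nupr1 (0.25 ± 0.06) and the amino acid transporter subunit Slc3a2 (0.23 ± 0.06), while the transcription factor Cebpg fell (-0.36 ± 0.06). Adjusted over the list alone, 12 of these 32 rose and 1 fell. Some lists share members: Bhlhe40 is in those of hypoxia and the clock, and Ddit4 in those of hypoxia and glucocorticoid targets.

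FGF signalling and its targets fell at 2 h (camera adjusted p = 4.07e-06, adjusted p = 0.101 with an estimated correlation). The feedback inhibitors Spry2 (-0.40 ± 0.09, adjusted p = 0.0218) and Dusp6 (-0.50 ± 0.12, adjusted p = 0.0378) passed over all genes. Adjusted over the list alone, 8 of 17 members were lower. The Spry2 call held in 31 of 39 alternatives. The Dusp6 call held in 21 of 39 and was lost on leaving out any of 9 libraries. The list mean was 0.29 ± 0.07 in vehicle and 0.00 ± 0.21 in ethanol (SD, n = 6 each; exact permutation p = 0.00216, adjusted 0.0152). The endoplasmic reticulum chaperones were lower (camera adjusted p = 0.00594, adjusted p = 0.294 with an estimated correlation), with Herpud1 (-0.32 ± 0.08) the member of 23 that passed over all genes and 2 lower when adjusted over the list alone. The list was not called without ethanol 2 h replicate 6 (mean difference -0.09 against -0.11 with it, adjusted p = 0.156), and the Herpud1 call held in 12 of 39 alternatives and was lost on leaving out any of 20 libraries. DNA methylation and histone deacetylation genes were lower as a list (camera adjusted p = 0.00212, adjusted p = 0.101 with an estimated correlation); none of 22 members passed over all genes and 2 were lower when adjusted over the list alone.

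Markers of other cell types moved with ethanol at 2 h as well. Endothelial markers were lower (camera adjusted p = 0.000495, adjusted p = 0.621 with an estimated correlation), with 16 of 17 members below 0 and Kdr at -0.62 ± 0.22 not passing. Head mesenchyme (camera adjusted p = 0.0165, adjusted p = 0.679 with an estimated correlation) and neural crest (camera adjusted p = 0.0139, adjusted p = 0.535 with an estimated correlation) were also lower, while primitive erythroid markers were higher (camera adjusted p = 0.0216, adjusted p = 0.717 with an estimated correlation). Without ethanol 2 h replicate 6 camera called none of these 4 lists, and their mean differences were -0.06 for endothelium, -0.08 for head mesenchyme, -0.10 for neural crest and 0.19 for erythroid markers, against -0.24, -0.21, -0.18 and 0.29 with it. No member of the 4 lists passed over all genes, and 1 head mesenchyme member, Twist1 (-0.38 ± 0.10), was lower when adjusted over the list alone. Erythroid list means spread widely within groups, at -0.29 ± 0.48 in vehicle and 0.00 ± 0.31 in ethanol (SD, n = 6 each). Camera with the preset correlation further placed the respiratory chain (adjusted p = 0.00219), cholesterol biosynthesis (0.0261), p53 targets (0.0400) and glycolysis (0.0400) higher, and ribosome biogenesis (0.0139) and Sonic hedgehog signalling (0.0257) lower. Without ethanol 2 h replicate 6 ribosome biogenesis (mean difference -0.05 against -0.11, adjusted p = 0.963), cholesterol biosynthesis (0.07 against 0.09, adjusted p = 0.156) and p53 targets (0.06 with and without it, adjusted p = 0.156) were not called. The adjusted p-values of the 6 lists with an estimated correlation were 0.696, 0.696, 0.294, 0.679, 0.687 and 0.626 in that order, and Sc5d (0.35 ± 0.08), a cholesterol enzyme, was the member that passed over all genes. Adjusted over the list alone, 5 of 26 p53 targets were higher, with Sesn1 at 0.28 ± 0.08 and Sesn2 at 0.20 ± 0.06.

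At 2 h camera thus called 18 of 42 lists, 10 up and 8 down, and none with an estimated correlation. Directional fry called 7: hypoxia, FGF, circadian clock, integrated stress response, DNA methylation, antioxidant and glucocorticoid targets. The permutation of list means called 8: the same without DNA methylation, plus endoplasmic reticulum chaperones and glycolysis. As covariates subtracted before deposit can favour the real split, these 8 calls do not exclude chance. Mixed fry called 15 lists. Among them were lists that camera did not call: immediate early genes (adjusted p = 5.38e-12), apoptosis machinery (2.68e-05) and differentiating neuron (0.000159). Others were cytosolic heat shock proteins (0.000363), primary cilium assembly (0.00392) and S phase (0.0217). The 24 lists not called by camera had camera adjusted p-values from 0.0607 to 0.966, and the mean, median and test of a list differed in sign in 6 of them. They were S phase, cardiac muscle, primary cilium assembly, cytosolic ribosomal proteins, apoptosis machinery, ventral and dorsal neural tube, surface ectoderm, ethanol and aldehyde metabolism, cytosolic heat shock proteins, G2 and M phase, Wnt, Notch and BMP signalling, retinoid metabolism, one-carbon metabolism, immediate early genes, differentiating neuron, neural progenitor, forebrain, midbrain and hindbrain, macrophage, endoderm and yolk sac, and sex-linked genes. Members of these lists that passed were Casp2 (-0.32 ± 0.06), Bik (0.29 ± 0.06) and Birc2 (0.19 ± 0.05) of the apoptosis machinery, Exo1 (-0.32 ± 0.07) of S phase, Kif3b (-0.40 ± 0.10) and Tmem67 (-0.19 ± 0.05) of the cilium, Gbx2 (0.22 ± 0.05), Tubb3 (0.28 ± 0.07), Hspa8, Ier3 and Myc. Most alternatives ended the calls of Kif3b (kept in 11 of 39), Tmem67 (13 of 38), Birc2 (13 of 38) and Tubb3 (16 of 39), each of which was lost on leaving out any of 15 to 19 libraries. Shh pathway genes did not pass singly, with Sufu at -0.41 ± 0.12 and Gli1 at -0.20 ± 0.07. The sex-linked list joins Xist and Tsix with Y-linked genes, which differ between the sexes in opposite directions. Its lack of a call therefore does not show that the sexes were balanced.

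**Figure D2:**
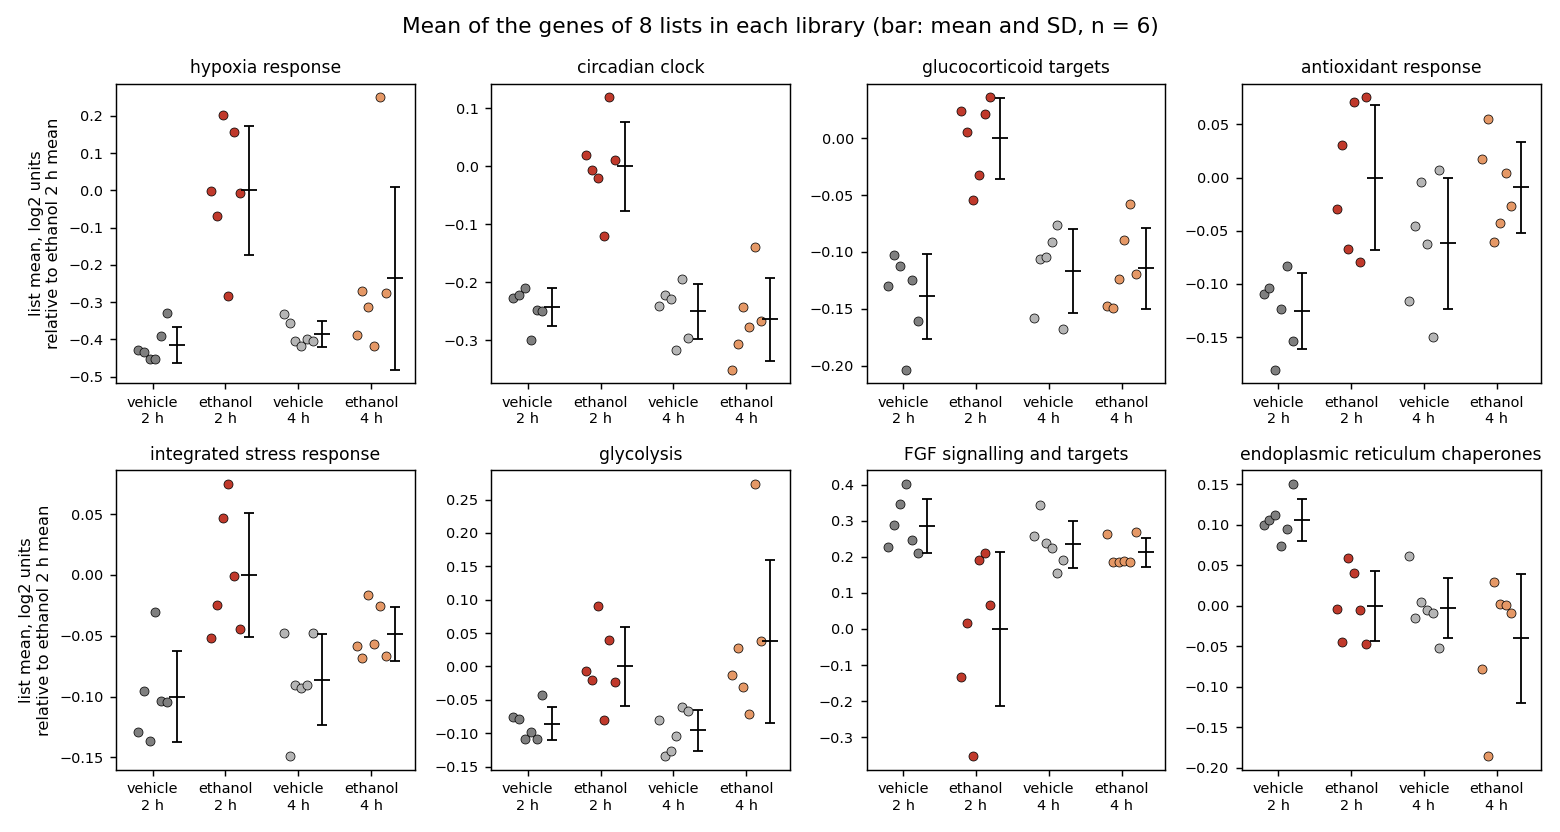
Mean of the genes of 8 fixed lists in each library, in log2 units relative to the ethanol 2 h mean, by group; points are libraries and bars the mean ± SD (n = 6). These 8 lists passed between ethanol and vehicle at 2 h by exact permutation, which can favour the real split. Ethanol 4 h replicate 5 stood above the other ethanol 4 h libraries for hypoxia (0.25) and glycolysis.

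The second comparison asked what differed 4 h after ethanol. Here 31 genes passed, 13 higher and 18 lower, and the largest difference was 0.61. Arhgap45, a Rho GTPase-activating protein, was 0.61 ± 0.08 log2 units higher (n = 6 per group, adjusted p = 0.00267), the β-tubulin Tubb6 0.47 ± 0.06 higher (adjusted p = 0.00267) and Pycard, the inflammasome adaptor, 0.32 ± 0.04 higher (adjusted p = 0.00267). Hspa8 was again lower (-0.54 ± 0.11, adjusted p = 0.0474), as were the cholesterol enzyme Hsd17b7 (-0.42 ± 0.08) and the splicing factor Srsf6 (-0.32 ± 0.04, adjusted p = 0.00306). All 6 ethanol libraries lay on the same side of the vehicle mean for each of these genes.

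The remaining rises were Trim6 (0.53 ± 0.09), Asap3 (0.52 ± 0.10), the class I histocompatibility rows H2-D1 (0.42 ± 0.07) and H2-L (0.33 ± 0.06), which may report the same transcripts and so count 1 rise as 2, the ganglioside synthase B4galnt1 (0.38 ± 0.06), cathepsin L (Ctsl, 0.36 ± 0.06), Emilin3 (0.32 ± 0.06), Art5 (0.29 ± 0.06) and Zfp763 (0.29 ± 0.06). The remaining falls were Adpgk (-0.38 ± 0.07), an ADP-dependent glucokinase, Tmem55a (-0.35 ± 0.06), Vps51 (-0.34 ± 0.06), Trmt10a (-0.33 ± 0.06), the glycosyltransferase Alg8 (-0.33 ± 0.06), the mitochondrial carrier Slc25a29 (-0.33 ± 0.06), the centromere protein Cenpn (-0.32 ± 0.06), the methyl-CpG binding domain protein Mbd3 (-0.26 ± 0.04) and Spout1 (-0.24 ± 0.05). Adjusted p-values from limma for these genes lay between 0.0131 for B4galnt1 and 0.0474 for Spout1. The Spout1 call held in 11 of 38 alternatives. With the widened spread 4 genes passed: Pycard, Arhgap45, Tubb6 and Srsf6. Library weights gave 262 genes at 4 h and 199 at 2 h, a fit on the 4 h libraries alone gave 23 genes of which 6 were among the 31, and without vehicle 4 h replicate 2 the count was 6.

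Camera called 8 of 42 lists at 4 h with the preset correlation and none with an estimated correlation, where the smallest adjusted p was 0.944. Neither directional fry (smallest adjusted p = 0.869) nor the permutation of list means (smallest adjusted p = 0.273) called any. Mixed fry called 2, integrated stress response (adjusted p = 0.00592) and glycolysis (adjusted p = 0.015). The lists called by camera were glycolysis, cardiac muscle and hypoxia response upward, and ribosome biogenesis, cholesterol biosynthesis, primitive erythroid, respiratory chain and cytosolic ribosomal proteins downward, with camera adjusted p-values from 0.000545 to 0.0190. In glycolysis none of 18 members passed over all genes and 6 were higher when adjusted over the list alone, with Pfkm at 0.31 ± 0.07 and the lactate exporter Slc16a3 at 0.72 ± 0.18. In the hypoxia list 3 of 23 were higher when adjusted over the list alone, with Bnip3 at 0.99 ± 0.24, and in ribosome biogenesis 3 of 29 were lower, with Nip7 at -0.34 ± 0.08. Hsd17b7 was the member of cholesterol biosynthesis that passed, over all genes and over the list alone, and the other 4 called lists had none by either adjustment. All 16 erythroid members were below 0, with a list mean of -0.06 ± 0.45 in vehicle and -0.39 ± 0.34 in ethanol (SD, n = 6 each). Without ethanol 4 h replicate 5 camera no longer called hypoxia, glycolysis or cytosolic ribosomal proteins. The mean difference of the hypoxia list was then 0.05 against 0.15 with that library (camera adjusted p = 0.411). It was 0.09 against 0.13 for glycolysis (adjusted p = 0.0527) and -0.02 against -0.04 for cytosolic ribosomal proteins (adjusted p = 0.341). The 34 lists not called by camera had camera adjusted p-values from 0.0698 to 0.994, and the mean, median and test differed in sign in 10 of them. Among the 34, the circadian clock, FGF, antioxidant, glucocorticoid and integrated stress response lists stood at 0.657, 0.784, 0.433, 0.836 and 0.433. In these 34, Hspa8 and Mbd3 were the members that passed over all genes.

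The third comparison set the ethanol response at 4 h against that at 2 h. The response differed for 20 genes, 7 more positive and 13 more negative at 4 h; 18 of them had passed at 2 h, 1 (Hsd17b7) had passed at 4 h, and Cth, named outside the rule, had passed at neither time. Rsrp1 differed by 1.51 ± 0.20 (adjusted p = 0.00405), from -1.41 at 2 h to 0.10 at 4 h, and Ciart by -1.35 ± 0.20 (adjusted p = 0.0113), from 1.09 to -0.25. In the same upward sense as Rsrp1 were Asxl2 (0.85 ± 0.14), Ankrd10 (0.81 ± 0.13), Wsb1 (0.65 ± 0.10), Zfp280d (0.53 ± 0.09) and Grpel2 (0.37 ± 0.07). In the same sense as Ciart were Hilpda (-0.70 ± 0.12), Pde4b (-0.65 ± 0.12), Slc35e4 (-0.51 ± 0.08), Sephs2 (-0.45 ± 0.07) and Wdr73 (-0.38 ± 0.06). Bhlhe40 did not pass this test (-1.45 ± 0.34, adjusted p = 0.0930). No gene passed with the widened spread, and the count was 6 without ethanol 2 h replicate 2 and 101 without ethanol 2 h replicate 5.

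A further question was whether the 2 h response was seen again at 4 h. Trim6 and B4galnt1 were higher and Hspa8 and Fiz1 lower at both times, where independent lists of these sizes would share 0.14 genes upward and 0.15 downward. Fiz1 stood at -0.19 ± 0.04 at 2 h and -0.22 ± 0.04 at 4 h. The 4 h call held in 18 of 39 alternatives for Hspa8 and in 16 of 38 for Fiz1, and was lost on leaving out any of 15 libraries for either gene. Of the 365 genes that passed at 2 h, 251 (68.8%) had the same sign at 4 h, with a median 4 h difference of 0.06 in the 2 h direction against a median size of 0.33 at 2 h. Over all 462 splits of the 4 h libraries that share, or its mirror, was as large in 136 (exact permutation p = 0.294, median 62.5%), and the median difference was as large in 44 (exact permutation p = 0.0952). Adjusted over those genes alone, 35 passed at 4 h, 32 of them with the same sign. Across all genes, which are not independent replicates, the differences at the 2 times had a Pearson correlation of 0.11 and a Spearman correlation of 0.10. The Pearson value was no larger than chance gives, with a median size of 0.11 over other splits of the libraries.

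**Figure D3:**
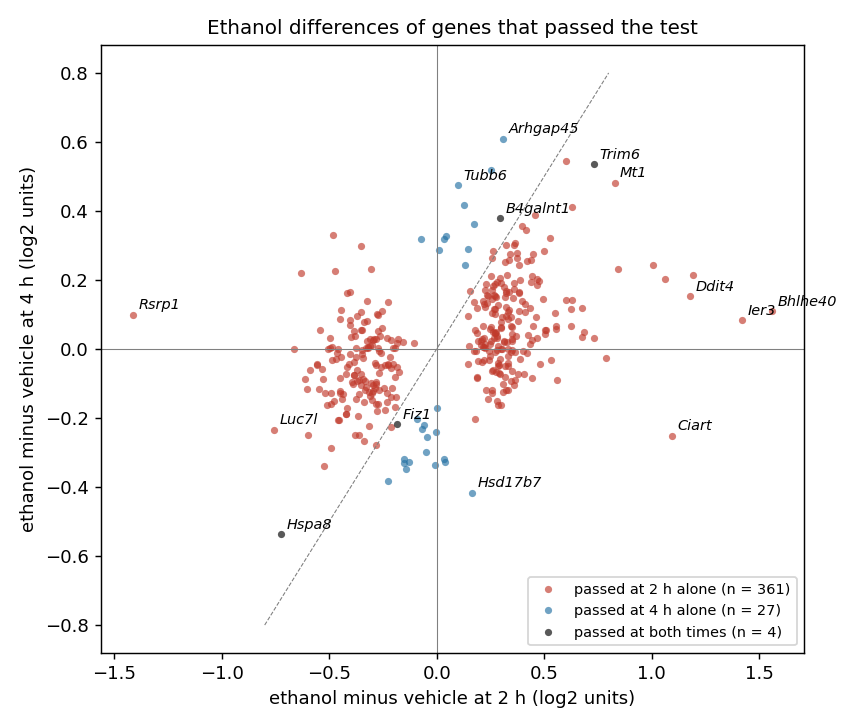
Ethanol minus vehicle difference at 2 h (x axis) and 4 h (y axis), both in log2 units, for genes that passed at either time; colours mark the time, and the dashed line marks equal differences. Of the 365 genes that passed at 2 h, 4 also passed at 4 h, and Bhlhe40 and Ier3, the largest rises at 2 h, stood at 0.11 and 0.08 at 4 h.

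The last comparisons followed each treatment from 2 h to 4 h. In vehicle no gene passed by limma; 1007 genes had an unadjusted p under 0.05, where 931.1 would be expected by chance, and the smallest adjusted p was 0.101. In ethanol 699 genes passed, 254 higher and 445 lower at 4 h. The largest falls were in genes that had risen at 2 h: Bhlhe40 (-1.31 ± 0.24), Ier3 (-1.28 ± 0.18), Ciart (-1.16 ± 0.14), Arrdc3 (-1.03 ± 0.14), Stc1 (-0.87 ± 0.13) and Adm (-0.79 ± 0.16). The largest rises were Rsrp1 (1.46 ± 0.14), Ankrd10 (1.05 ± 0.09), the matrix protein Fbln2 (0.67 ± 0.15), Asxl2 (0.64 ± 0.10), Dmrta1 (0.63 ± 0.15) and the splicing-related Rbm25 (0.63 ± 0.12). Of the 699 genes, 142 had also passed for ethanol at 2 h, all 142 with the opposite sign, as the shared ethanol 2 h libraries favour. With the widened spread 14 genes passed, and a fit on the ethanol libraries alone gave 36.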

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

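The explanations in this part, and the use of tests to weigh them, were chosen only after the results were seen. Library weights, leaving out each library, the interaction test and the splits for the correlation between the times had been fixed beforehand. The other splits of the libraries had not.

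For 20 genes, 12 of them named by the rule, the ethanol response differed between the times by the interaction test of limma. The response was more positive at 4 h for Rsrp1 (1.51), Wsb1 (0.65), Ankrd10 (0.81), Asxl2 (0.85), Zfp280d (0.53) and Grpel2 (0.37), with adjusted p-values from 0.00405 for Rsrp1 to 0.0322 for Grpel2. It was more negative at 4 h for Ciart (-1.35), Slc35e4 (-0.51), Sephs2 (-0.45), Wdr73 (-0.38), Hilpda (-0.70) and Pde4b (-0.65), with adjusted p-values from 0.0113 for Ciart to 0.0269 for Pde4b.

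In 18 of 316 gene and group pairs (5.70%) 1 library lay far from the other 5, by the ratio of its gap to the range of the group; chance gives about 1 in 20. Ethanol 4 h replicate 5 stood above its group for Ddit4 (0.09 against -0.75 in the nearest library, ratio 0.695) and Stc1 (-0.26 against -0.83, ratio 0.628). Ethanol 4 h replicate 2 stood apart for Rsrp1 (ratio 0.716), Sall2 (0.743) and Alg8 (0.680), replicate 1 for B4galnt1 (0.716) and replicate 4 for Zfp763 (0.732). Among the ethanol 2 h libraries, replicate 3 stood apart for Sall2 (0.744) and Herpud1 (0.780), replicate 5 for Arhgap45 (0.670) and Fbln2 (0.634), and replicate 4 for Emilin3 (0.628). In vehicle at 2 h the libraries were replicate 4 for Ddit4 (0.635) and Wdr73 (0.790), replicate 1 for Rsrp1 (0.644) and replicate 3 for H2-D1 (0.646). In vehicle at 4 h replicate 1 stood apart for Ddit4 (0.657) and Mbd3 (0.692).

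Other splits of the libraries were compared with the real one, 100 in each case with the real split counted. At 2 h 1 split, the real one, gave as many as 365 genes, and the highest other gave 6. The real split also stood alone at 4 h (1 split, 31 genes, highest other 2) and for the interaction (1 split, 20 genes, highest other 2). Because covariates appear to have been subtracted around the real groups before deposit, these comparisons favour the real split, and chance is not excluded by them. For time in ethanol 3 splits reached 699 and the highest other gave 1271, so some other arrangement of these libraries holds a structure larger than the time difference. For time in vehicle all 100 splits reached the real count of 0 by limma (1007 genes at an unadjusted p under 0.05), and the highest other gave 1. For the lists at 2 h 3 splits reached 18 and the highest other also gave 18. The median over the other splits was 10, so camera with the preset correlation calls many lists in splits other than the real one. Unbalanced splits keep part of any ethanol difference, so this median is not a value without ethanol. For the lists at 4 h 19 splits reached 8 (highest other 11), and for the correlation between the times 44 splits reached 0.11 (highest other 0.49), so chance is not excluded for either.

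The first pattern is that far more genes passed at 2 h (365) than at 4 h (31). Ethanol differences followed transcript length across genes (Spearman -0.30 at 2 h and 0.11 at 4 h). The change from 2 h to 4 h followed it too, by -0.22 in vehicle, where no gene passed, and by 0.23 in ethanol. A trend with length thus also arose without ethanol. The median length was 4289 nucleotides for genes called lower with ethanol at 2 h and 2395 for those called higher. This trend, with that of GC content, is excluded as the whole cause but not as a part, since 386 genes passed at 2 h, 287 of them among the 365, and 40 at 4 h once it was removed from each library. Unequal spread between libraries is a possible explanation, because library weights gave 199 genes at 2 h and 262 at 4 h. The weights were low for ethanol 2 h replicates 3 (0.24), 2 (0.32) and 6 (0.35). Replicates 2 and 6 also held 0.66 and 0.44 of the 2 removed dimensions, so the weights do not separate this explanation from the next. Whether dimensions removed before deposit made the errors too small cannot be told apart from an effect of ethanol, because their part between groups is not in the table; the widened spread left 29 genes at 2 h and 4 at 4 h, and a response that had faded by 4 h stays open.

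The second pattern is that markers of endothelium, head mesenchyme and neural crest were lower and erythroid markers higher with ethanol at 2 h. A larger neural share of the dissected tissue would lower all of them alike; the erythroid list less the endothelial list differed by 0.53 (exact permutation p = 0.104), which is too uncertain to exclude it. With the endothelial, mesenchymal and erythroid means as covariates the hypoxia list differed by 0.44, against 0.41 without them (fry adjusted p = 0.00706). A change in composition that follows these means linearly therefore did not carry the rise of the hypoxia list. Changes that these means do not follow, such as in neural crest or neural regions, were not tested. Without ethanol 2 h replicate 6 the calls of all 4 lists were lost and the directions stayed, with -0.06 against -0.24 for endothelium, -0.08 against -0.21 for head mesenchyme, -0.10 against -0.18 for neural crest and 0.19 against 0.29 for erythroid markers. An effect of ethanol on these cell types stays open and was not tested.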

How the results depend on the processing

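Alternatives marked here as added were chosen after seeing the data: the fit without the removed dimensions, the filter on residual spread, the length and GC correction, marker means as covariates, the widened spread, leaving out ethanol 2 h libraries 2 and 3, and the permutation of list means. The cause of a change was not tested except where the alternative itself sets it (a threshold, fewer libraries). No named gene that passed turned direction in any alternative. Of the settings tried for those genes, 345 of 1830 at 2 h, 245 of 968 at 4 h, 61 of 454 for the interaction and 27 of 468 for time in ethanol no longer passed. A stricter filter on low values and a mean-variance trend were not run, as the table gives no level; depth is unknown, so what it limits cannot be stated.

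With library weights 199 genes passed at 2 h, 262 at 4 h, 4 for time in vehicle and 128 for time in ethanol. With quantile normalization 17 passed at 4 h, 2 for the interaction (1 higher, 1 lower) and 280 for time in ethanol, and the correlation was 0.19. With the sex-linked covariate 214 passed at 2 h (200 of them among the 365) and 13 for the interaction. That covariate, the mean of Y-linked genes less Xist, ran from -1.50 to -0.54 in the vehicle 2 h libraries. In the ethanol 2 h libraries it ran from -1.03 to 1.58. Because covariates appear to have been subtracted before deposit, the sex of an embryo cannot be read from these values with certainty. Neither they nor this fit tell whether the sexes were balanced at 2 h, so an unequal share is not excluded and not shown. At an adjusted p under 0.1 the counts were 723, 189, 72 and 1257 for 2 h, 4 h, the interaction and time in ethanol, and with a difference of at least 0.5 they were 50, 4, 12 and 36. Fits on the compared groups alone gave 157 at 2 h (126 of them among the 365), 23 at 4 h (6 among the 31) and 36 for time in ethanol (34 among the 699). Without the removed dimensions 598, 175, 83 and 2 genes passed at 2 h, at 4 h, for the interaction and for time in vehicle. The widened spread gave 29, 4, 0 and 14 for 2 h, 4 h, the interaction (2011 genes at an unadjusted p under 0.05 by limma) and time in ethanol. The residual spread filter gave 17 at 4 h and 457 for time in ethanol, the length and GC correction 12 for the interaction, and marker means as covariates 42 for the interaction, a correlation of 0.0250 and 9 lists at 2 h. Without ethanol 2 h libraries 2 and 3, 78 genes passed at 2 h (56 of them among the 365), 128 at 4 h, 11 for the interaction, 4 for time in vehicle and 254 for time in ethanol, and the correlation was 0.19. With an estimated correlation camera called 0 lists at either time, directional fry called 7 at 2 h and 0 at 4 h, and the permutation of list means 8 and 0. Mixed fry called 15 at 2 h and 2 at 4 h.

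Replicate numbers did not pair the libraries: same-numbered vehicle and ethanol libraries had residual correlations from -0.06 to 0.41 at 2 h and from -0.13 to 0.14 at 4 h, and 1 of 6 correlated best with its own number at each time. Ethanol libraries of the 2 times had -0.20 to 0.67, with 2 of 6 best with their own number, and vehicle libraries -0.15 to 0.10, with 1 of 6. With the replicate block 343 genes passed at 2 h, 60 at 4 h, 18 for the interaction and 709 for time in ethanol.

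Leaving out 1 library gave 85 to 674 genes at 2 h. The count was 232, 241, 243 and 182 without vehicle 2 h replicates 1, 2, 5 and 6, 85 without ethanol 2 h replicate 2 and 674 without replicate 5. At 4 h the range was 6 to 100: 100, 52 and 60 without ethanol 2 h replicates 3, 5 and 6, 16, 6, 7, 58 and 64 without vehicle 4 h replicates 1, 2, 4, 5 and 6, and 9 and 20 without ethanol 4 h replicates 1 and 2. For the interaction it was 6 to 101: 13, 12 and 12 without vehicle 2 h replicates 1, 5 and 6, 6, 101 and 34 without ethanol 2 h replicates 2, 5 and 6, 12 and 13 without vehicle 4 h replicates 2 and 4, and 12, 10, 11, 33 and 11 without ethanol 4 h replicates 1, 3, 4, 5 and 6. For time in vehicle it was 0 to 5, with 5 without ethanol 2 h replicate 2 and 1 without vehicle 2 h replicate 2 or 3 or vehicle 4 h replicate 6. For time in ethanol it was 347 to 1148: 347 and 1148 without ethanol 2 h replicates 2 and 5, and 432 and 404 without ethanol 4 h replicates 4 and 6. The correlation ranged from -0.0198 without ethanol 4 h replicate 2, where its sign turned, to 0.18 without replicate 4 of that group. It was also 0.18 without ethanol 2 h replicate 3 or vehicle 4 h replicate 6, and 0.05, 0.06 and 0.02 without ethanol 2 h replicate 5, vehicle 4 h replicate 1 and vehicle 4 h replicate 5. The lists called were 10 to 19 at 2 h, with 10 without ethanol 2 h replicate 6, and 5 to 9 at 4 h, with 5 without ethanol 4 h replicate 5.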

Other observations

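The adjusted p-values of single genes in this part come from the limma comparisons described above, whose contrasts were fixed beforehand. The other tests were chosen only after the results were seen. Clk4, Luc7l3, Srsf5, Epo, Cirbp and Rbm3 fall outside the rule for named genes and were chosen after their values were seen.

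Some genes of splicing regulators were lower with ethanol at 2 h. In a set of 24 such genes put together after some of them had been seen to fall, 5 passed as lower, 1 as higher and 18 did not pass. The lower ones were Rsrp1, Luc7l, Clk1, Clk4 (-0.46 ± 0.11, adjusted p = 0.0346) and Luc7l3 (-0.27 ± 0.07, adjusted p = 0.0322). The higher one was Srsf5 (0.34 ± 0.07, adjusted p = 0.0200). At 4 h Srsf6 was the member that passed, as lower, and the difference of Luc7l was -0.23 ± 0.08 (adjusted p = 0.271). Because the set was built on these libraries, no test of it as a group is given.

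Epo, which encodes the hormone erythropoietin and is induced by low oxygen, was higher with ethanol at 2 h (0.37 ± 0.05, adjusted p = 0.000142) and stood at 0.04 ± 0.05 at 4 h (adjusted p = 0.851). The difference between the times passed (-0.33 ± 0.06, adjusted p = 0.0480). Hypoxia list means in the ethanol 4 h libraries lay between -0.42 and -0.27, except for replicate 5 at 0.25.

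The third pattern is that Hspa8 was lower and Cirbp, an RNA-binding protein induced by mild cold, higher with ethanol at 2 h (Cirbp 0.60 ± 0.11, adjusted p = 0.00715, and 0.54 ± 0.11 at 4 h, adjusted p = 0.0564). One hypothesis is that ethanol lowered the temperature of the dam, which the labels do not record. Rbm3, which is also induced by cold, differed by 0.20 at 2 h (95% interval 0.03 to 0.37, adjusted p = 0.237); its interval overlaps that of Cirbp (0.36 to 0.84), which leaves the hypothesis open at 2 h. At 4 h Rbm3 stood at -0.02 (-0.19 to 0.15), below the interval of Cirbp (0.31 to 0.78). Rbm3 is 1 gene, and it is not known whether it would follow cooling as Cirbp does, so this does not decide the hypothesis at that time. A fall of cytosolic chaperones as a class by about the change of Hspa8 is excluded, while a smaller one is not, since the 20 other members of the list differed by 0.0121 on average (SD 0.23 over members, exact permutation p = 0.961).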
